A study of Homo sapiens with 6 samples.

How the data were processed

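RNA from 6 samples labelled HepG2 was sequenced after preparation with a stranded kit that selects messenger RNA, per the labels' protocols. The deposited table holds 1 TPM value (a unit that divides each gene's reads by its length and scales every library to a sum of 1000000) per gene and library, with 2 decimals, beside each gene's length and the authors' functional annotation. Per the submitters' processing notes, HISAT2 2.1.0 and RSEM 1.3.3 were used with the genome build GRCh38.p13. The notes give neither the role of each tool nor the gene annotation, and whether reads were assigned by strand is not given in the sources used here. Values of genes that overlap another gene, or that share reads with close copies, are therefore uncertain. That applies to the metallothionein genes, FTL with its many pseudogenes, HSPA1A, KRT17 and ALPP.

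TPM keeps no read total, so the depth behind each value is unknown and no interval or detection floor was computed. The table listed 62703 genes, of which 20966 had no gene symbol and 30367 had a value above 0 in at least 1 library. Gene types and coordinates came from the GENCODE 29 annotation on GRCh38, which held 58279 of the gene identifiers. All 851 genes of the fixed lists were found in the table, 1 of them by its gene identifier through a separate gene name reference.

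Libraries were grouped by their titles into 3 given palmitic acid alone (PA) and 3 given palmitic acid with HQF and copper chloride. No source used here says that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Genes with a mean of at least 1 TPM over the 6 libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the spread), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Every log2 fold change is the mean of the HQF and copper libraries minus the mean of the PA libraries on the log2(TPM + 1) scale, which understates the change of genes with low values. TPM is not a count, so no count model was used.

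Before the data were examined, 42 gene lists were written for fat, copper, stress, mitochondria, inflammation, growth and hepatocyte state, with markers of other cells, ribosomal proteins, histones and housekeeping genes as technical checks. The 34 lists with at least 5 genes tested were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. The same lists were tested with the correlation estimated from the libraries and with fry, which asks whether a list's genes moved on balance 1 way and compares them with no other genes. Counts of list members adjusted over the list alone are given where they differ from those over all genes tested.

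The genes to be named were set by a rule before the data were examined. It took the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, no overlap between the groups, a mean of at least 5 TPM in the higher group and a real gene symbol. It also took up to 4 members of each list past the threshold by size of change, or the 2 with the smallest p where none passed, and 21 genes of copper, fat and stress biology whatever their values. Genes named after their values were seen are marked as such.

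The alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter on low values, a minimum mean of 5 TPM, median-of-ratios and TMM scaling of the TPM values, rescaling without mitochondrial DNA genes and the 20 most abundant genes, quantile normalization, the replicate number as a block with and without median-of-ratios scaling, a robust spread, no trend in the spread, protein-coding genes only, and leaving out each library in turn. Transcript testing and count models were not run, because the table holds neither transcripts nor counts. Chosen after seeing the data were the removal of a lowess trend (span 0.3) on gene length, or on length and GC content, in each library, the length correction together with the block, and the omission of genes shorter than 200 bases. GC content was known for 97.0% of the genes tested. Gene sets of the authors' annotation columns, from 10 to 300 genes in size, were also tested with camera after the data were seen.

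The steps were tested on simulated data for the comparison of the 2 groups over 13466 genes, in 5 runs with 200 changed genes each. They recovered 32.5% of genes changed 1.5-fold, 78.8% of those changed 2-fold and 98.8% of those changed 4-fold, and 5.3% of the calls were false. The noise in these runs was independent between genes, without an outlying library or a trend with gene length. These rates may therefore not hold for the real libraries. Data were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.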

Results

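Gene expression was measured in 6 libraries labelled HepG2, the name of a line from a human liver tumour that is widely used as a liver cell model. All 6 samples had been given 750 µM palmitic acid, a saturated fatty acid, to model the fat-loaded cells of fatty liver disease. In 3 libraries, the PA group, this was the only treatment the labels give, and it lasted 24 h. In the other 3 the cells treated with palmitic acid were then given 0.5 µM HQF, described in the series title as a pseudo-natural flavonol (flavonols are plant polyphenols), together with 5 µM copper chloride for 24 h. No untreated samples, and none with HQF or copper alone, were analysed here, so the comparison is that of the pair against palmitic acid alone. The labels call the 24 h of the PA group a pre-treatment. They do not say whether the PA cells were kept for the second 24 h too, in palmitic acid or not, or whether they received a vehicle. A difference in total time between the groups is therefore not excluded.

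Read totals are unknown, because TPM keeps none. Between 13241 and 13737 genes had at least 1 TPM per library, and transcripts of mitochondrial DNA took between 10.1% and 12.985% of the TPM sum. Across genes, log2(TPM + 1) correlated between 0.970 and 0.979 within the PA group, between 0.982 and 0.986 within the HQF and copper group, and between 0.966 and 0.980 across groups. The first principal component, with 39.2% of the variance, placed PA replicate 3 (score 15.2) among the HQF and copper libraries (6.39 to 22.1), apart from PA replicates 1 and 2 (-37.6 and -24.3). On the second, with 21.7%, PA replicate 3 stood alone at 33.9, while the other 5 libraries lay between -21.0 and 1.16.

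Transcripts of hepatocytes were nearly absent from all 6 libraries. Of 25 hepatocyte list genes, 20 had a mean under 1 TPM. ALB, which encodes serum albumin, was listed at 0 in all 3 PA libraries and in 2 of the HQF and copper libraries, and at 0.25 TPM in the other one. AFP, the fetal counterpart of albumin and chosen after its values were seen, had means of 0.407 and 0.500 TPM in the 2 groups. The 5 list genes above 1 TPM were CPS1, a urea cycle enzyme with a mean of 290.0 ± 30.4 TPM (SD, n = 6), and VTN, CEBPA, FOXA1 and ASGR1. Of these CPS1, FOXA1 and ASGR1 were named after their values were seen. None of the 5 passed the test between the groups, and camera gave the list an adjusted p of 0.948. Its median was -0.05, and the median log2 fold change of all genes tested was -0.047. Camera's direction, which is relative to the other genes tested and not to 0, was upward. All 15 housekeeping genes had at least 1 TPM in every library. KRT7, a keratin of bile duct and other simple epithelia, had a mean of 1181 ± 251 TPM (SD, n = 6), and CDKN2A, a cell cycle inhibitor gene, 361 ± 35.6 TPM. The lists for lipoprotein secretion and for drug and bile acid metabolism were likewise low, with 4 of 20 and 3 of 25 genes above 1 TPM on average. Among them SCARB1, a lipoprotein receptor gene, had a log2 fold change of -0.31 (limma adjusted p = 0.242) and NR1H3, a sterol-sensing nuclear receptor gene, 0.40 (adjusted p = 0.251).

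**Figure D1:**
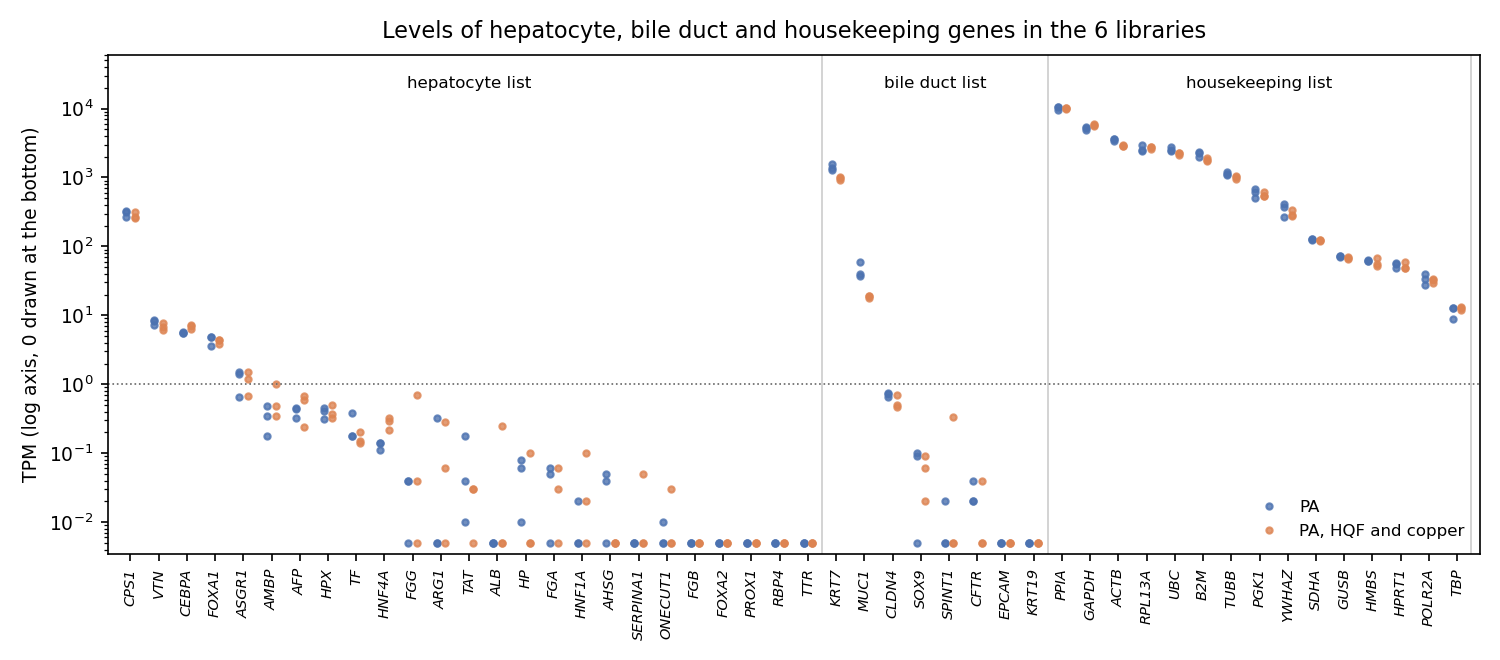
TPM on a log axis of the genes of the hepatocyte, bile duct and housekeeping lists in each of the 6 libraries, with 1 point per library, blue for PA and orange for PA with HQF and copper, values of 0 drawn at the bottom and a dotted line at 1 TPM. Of the 25 hepatocyte genes 20 had a mean under 1 TPM, while all 15 housekeeping genes lay above 1 TPM in every library.

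With HQF and copper, 9 of 28 tested targets of NRF2, the transcription factor that answers oxidants and electrophiles, were higher, HMOX1 first, and so were 2 of 4 tested metallothionein genes. Of the interferon-response genes 8 of 17 were lower, and of the inflammatory targets of NF-kB 3 of 19. The NRF2, interferon and NF-kB lists passed with camera's preset correlation but not with an estimated one (adjusted p = 0.0596, 0.155 and 0.0852). They passed with fry (adjusted p = 0.00632, 0.0143 and 0.00632), and metallothioneins were too few for a list test. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1 (chromosome 22, 35380361 to 35394214), rose from 129 ± 14.7 to 647 ± 14.3 TPM (SD, n = 3 per group), a log2 fold change of 2.32 (SE 0.094, limma adjusted p = 0.000126). NQO2, which encodes a quinone reductase (chromosome 6, 2987987 to 3028869), rose from 101 ± 4.63 to 221 ± 8.58 TPM (log2 fold change 1.12, SE 0.076, adjusted p = 0.00142). IL6, an inflammatory cytokine gene (chromosome 7, 22725884 to 22732002), fell from 156 ± 13.1 to 62.8 ± 8.61 TPM, a log2 fold change of -1.30 (SE 0.117, adjusted p = 0.00623). In all, 114 of 13466 genes passed the threshold, 35 higher and 79 lower, and 49 of them changed at least 2-fold, 11 higher and 38 lower. Of the 114, 91 were of the protein-coding type in GENCODE 29 and 15 had no symbol. Genes whose identifier that annotation lacks, such as SOD2, had no type and are not among the 91. The groups did not overlap for any of the 114 genes, nor for 20.7% of all genes tested, against 10% by chance. At an unadjusted p under 0.05 there were 1993 genes, against 673 expected by chance. The counts changed when single libraries were left out. Without PA replicate 1, 2 and 3, 29, 15 and 1356 genes passed (21, 12 and 140 at 2-fold). Without HQF and copper replicate 1, 2 and 3, 19, 6 and 9 genes passed (15, 6 and 8 at 2-fold). Such fits also hold fewer libraries, so a lower count need not mean that the library left out drove the calls. HMOX1 and NQO2 passed under every alternative tried, while 44 of 46 named genes lost their call without HQF and copper replicate 2.

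**Figure D2:**
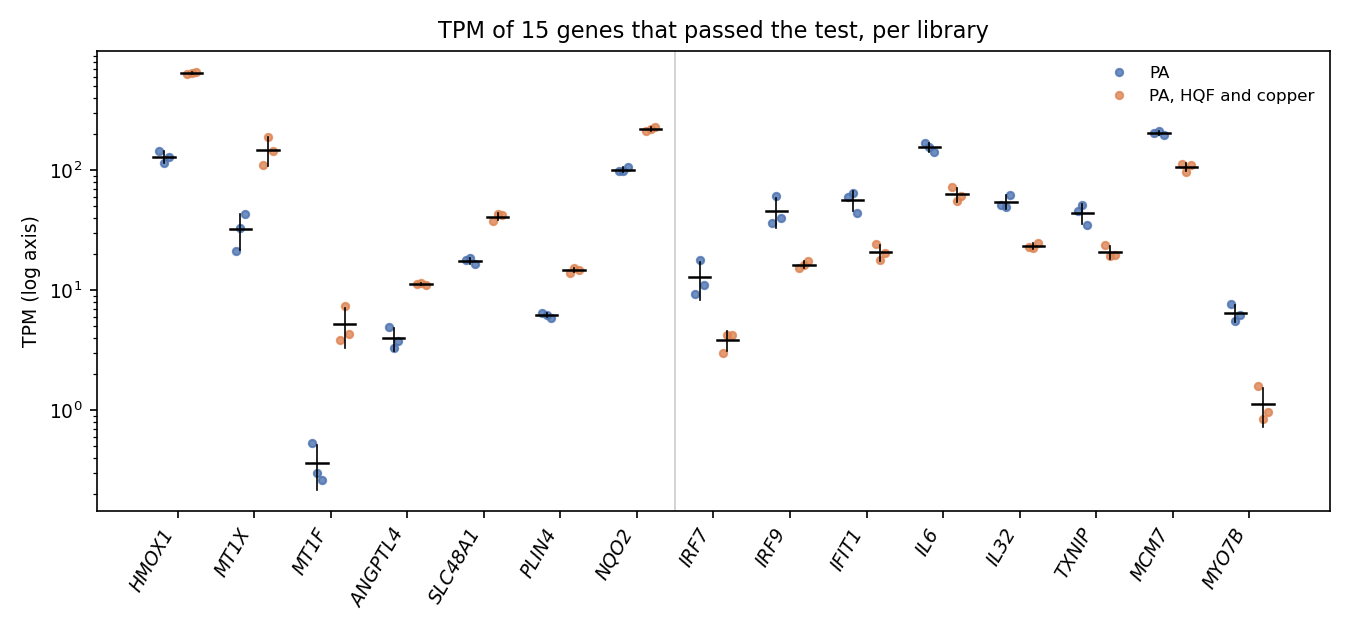
TPM on a log axis of 15 genes that passed the test, with 1 point per library, horizontal bars for the group means and vertical bars for 1 SD (n = 3 per group). For each gene the groups did not overlap, with HMOX1 near 129 TPM in PA and 647 TPM with HQF and copper, and IL6 at 156 and 62.8 TPM.

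**Figure D3:**
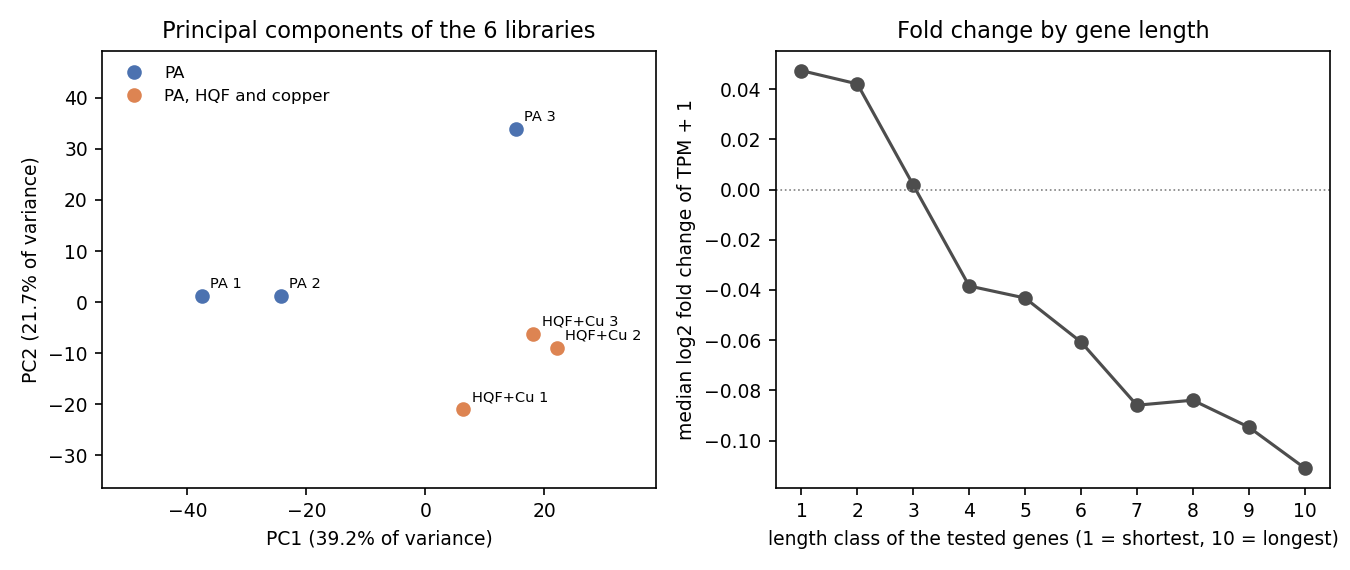
Left, scores of the 6 libraries on the first and second principal components of log2(TPM + 1), blue for PA and orange for PA with HQF and copper; right, the median log2 fold change of TPM + 1 within each of 10 equal classes of the tested genes ordered by length. PA replicate 3 stood apart from PA replicates 1 and 2, and the median fell from 0.05 in the shortest class to -0.11 in the longest.

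Of the 28 NRF2 targets, all tested, 27 had a log2 fold change above 0. Of them 9 rose and none fell (18 and 0 adjusted over the list alone), and the median log2 fold change was 0.40 (camera adjusted p = 1.79e-22; adjusted p = 0.0596 with an estimated correlation). Beside HMOX1, GCLM, a subunit gene of the enzyme that starts glutathione synthesis, rose by 0.97 (adjusted p = 0.0238). OSGIN1, an oxidant-induced gene, rose by 0.93 (adjusted p = 0.00402) and SRXN1, which encodes sulfiredoxin, by 0.87 (adjusted p = 0.0168). FTL, the ferritin light chain gene, rose from 6772 ± 453 to 11103 ± 413 TPM (log2 fold change 0.71, adjusted p = 0.0140), and SLC48A1, a heme transporter gene, from 17.6 ± 0.966 to 41.0 ± 2.88 TPM (1.17, adjusted p = 0.00513). CBR3, a carbonyl reductase gene (log2 fold change 1.06, adjusted p = 0.0388), and UNKL, a zinc finger gene (0.94, adjusted p = 0.0356), completed the rises among the 10 largest that belonged to none of the lists. FTL was also the only one of 15 iron and ferroptosis genes to pass (2 higher adjusted over the list alone). That list had a median of -0.04 but a mean of 0.02, and camera's direction relative to the other genes tested was upward (adjusted p = 0.291). NQO1, a quinone reductase gene (log2 fold change 0.45, adjusted p = 0.0360), was the only one of 5 tested targets of the aryl hydrocarbon receptor to pass, in a list with a median of -0.24 (camera adjusted p = 0.750; 1 higher and 1 lower adjusted over the list alone).

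Metallothionein genes, whose small proteins bind copper and zinc and whose similar sequences can share reads, were among the largest rises. MT1X (chromosome 16, 56682424 to 56684196) rose from 32.4 ± 10.7 to 148 ± 39.2 TPM (log2 fold change 2.18, SE 0.265, limma adjusted p = 0.0142) and MT1F from 0.363 ± 0.146 to 5.19 ± 1.92 TPM (2.15, adjusted p = 0.0137). MT2A was measured at 1103 ± 329 and 1915 ± 318 TPM, higher in 3 of 3 treated libraries (0.83, adjusted p = 0.135). MT1E, named after its values were seen, had a log2 fold change of 1.15 (adjusted p = 0.0646). These were the 4 of 12 metallothionein genes tested, all 4 past the threshold when adjusted over the list alone, and too few for camera. Among 24 tested copper-handling genes only SOD1, the copper and zinc superoxide dismutase gene, rose (log2 fold change 0.47, adjusted p = 0.0388). The list's median of 0.0039 and mean of -0.02 differed in sign (camera adjusted p = 0.450). The copper importer SLC31A1 (log2 fold change 0.12, adjusted p = 0.760), the copper pumps ATP7A (0.11, adjusted p = 0.848) and ATP7B (0.10, adjusted p = 0.860) and the metal-responsive factor MTF1 (-0.08, adjusted p = 0.868) did not pass. Neither did any of the 13 genes tied to copper-induced cell death (median -0.08, camera adjusted p = 0.904), among them FDX1 (0.23, adjusted p = 0.459) and DLAT (-0.19, adjusted p = 0.684). None of 15 zinc transport genes passed (median -0.12, camera adjusted p = 0.904). The zinc exporter SLC30A1 had a log2 fold change of 0.42 (adjusted p = 0.347), the zinc importer SLC39A1 -0.27 (adjusted p = 0.14) and SLC39A10 -0.56 (adjusted p = 0.284).

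All 17 tested interferon-response genes had a log2 fold change below 0. Of these 8 fell (15 adjusted over the list alone), and the median was -0.99 (camera adjusted p = 4.59e-17; adjusted p = 0.155 with an estimated correlation). The transcription factor gene IRF7 fell from 12.8 ± 4.52 to 3.84 ± 0.733 TPM (log2 fold change -1.48, limma adjusted p = 0.0396) and IRF9 (chromosome 14, 24161053 to 24166565) from 45.8 ± 12.99 to 16.3 ± 1.00 TPM (-1.40, adjusted p = 0.0188). The antiviral genes IFIT1 (-1.38, adjusted p = 0.0140) and IFIT3 (-1.26, adjusted p = 0.0140) fell as well, and so did IFIH1, a sensor of viral RNA outside the list (-1.32, adjusted p = 0.0388). Of 19 tested inflammatory targets of NF-kB, 3 fell (10 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 8.00e-07; adjusted p = 0.0852 with an estimated correlation). They were IL6, the cytokine gene IL32 (-1.18, adjusted p = 0.00839) and SOD2, a mitochondrial superoxide dismutase gene (-0.68, adjusted p = 0.0375). The list of fibrosis and matrix genes also fell (21 tested, median -0.30, camera adjusted p = 0.000595; adjusted p = 0.661 with an estimated correlation). Its only member past the threshold was ANKRD1, a target of mechanical signals (log2 fold change -1.32, adjusted p = 0.0237), with 4 lower when adjusted over the list alone.

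**Figure D4:**
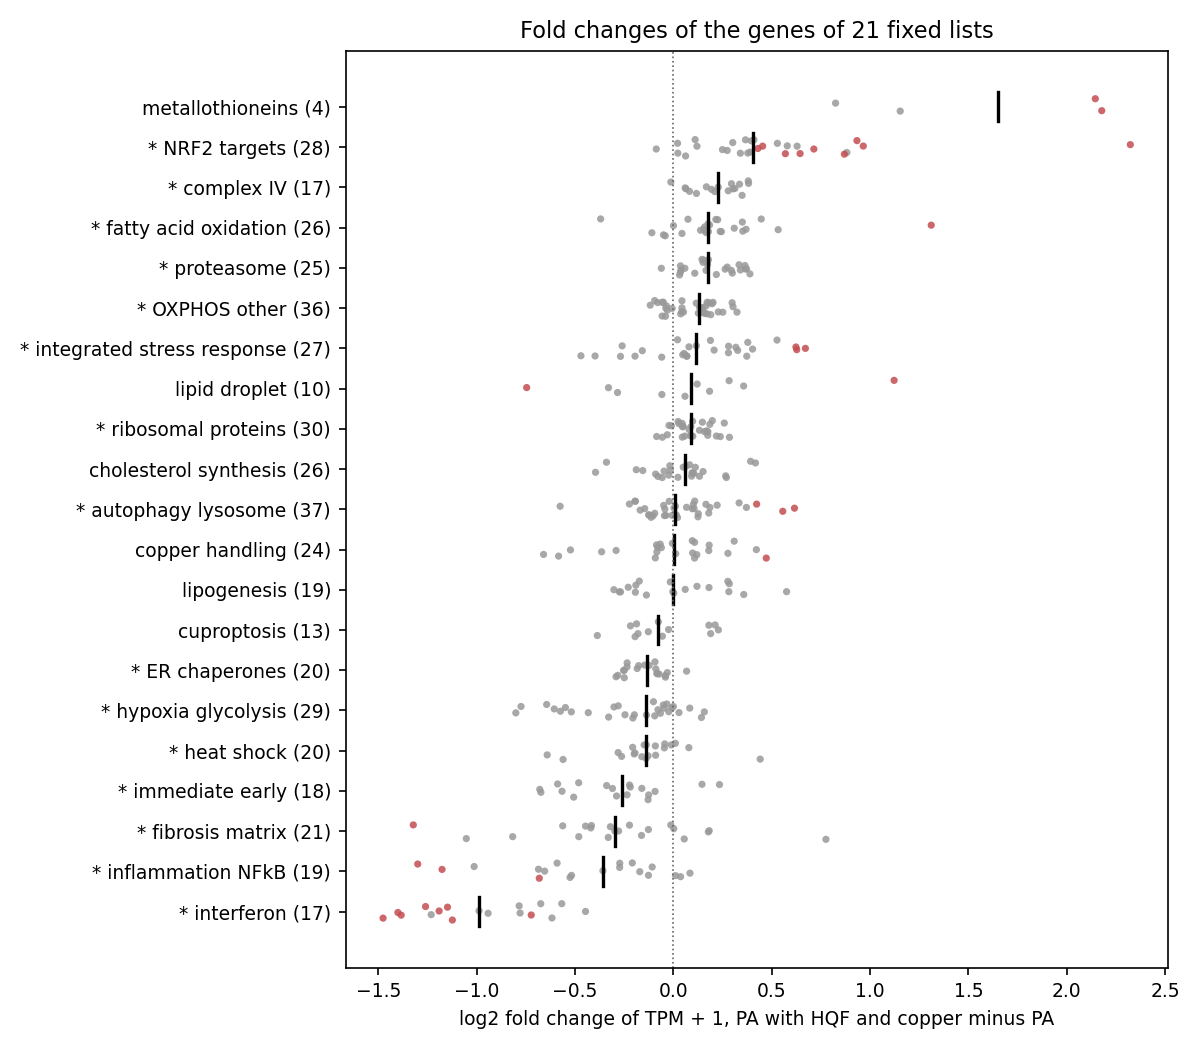
Log2 fold changes of TPM + 1, PA with HQF and copper minus PA, of the tested genes of 21 fixed lists, with 1 point per gene (red where the gene's adjusted p was under 0.05), a black bar at each list's median, a star before lists past the threshold with camera's preset correlation and the number of genes tested in parentheses. The interferon list lay lowest, with a median of -0.99, and the NRF2 list at 0.40.

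Among lipid lists only fatty acid oxidation passed, with camera's preset correlation but not with an estimated one (adjusted p = 0.172) or with fry (0.0962). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 3.99 ± 0.868 to 11.3 ± 0.277 TPM (log2 fold change 1.31, limma adjusted p = 0.0140). It was the only one of 26 tested members of the fatty acid oxidation list past the threshold (4 adjusted over the list alone). That list had a median of 0.18 (camera adjusted p = 6.54e-07). CPT1A, the entry enzyme of mitochondrial fat oxidation, had a log2 fold change of 0.23 (adjusted p = 0.460) and its regulator PPARA -0.05 (adjusted p = 0.925). Of 10 tested lipid droplet genes, the droplet coat gene PLIN4 rose from 6.19 ± 0.266 to 14.7 ± 0.631 TPM (1.12, adjusted p = 0.00921). The lipase gene MGLL fell from 30.4 ± 4.29 to 17.6 ± 1.25 TPM (-0.75, adjusted p = 0.0478; camera adjusted p of the list = 0.449). Adjusted over the list alone, 1 was higher and 2 lower. PLIN2, the droplet coat gene of most cells, was measured at 0.293 ± 0.136 and 0.240 ± 0.0436 TPM, and the fatty acid receptor gene CD36 at 0.070 ± 0.010 and 0.030 ± 0.020 TPM, both below the level tested. None of 19 lipogenesis genes passed, with a median of -0.0025 and a mean of 0.02 (camera adjusted p = 0.562). SREBF1 (-0.17, adjusted p = 0.623), FASN (-0.23, adjusted p = 0.324), SCD (-0.14, adjusted p = 0.732) and ELOVL6 (0.58, adjusted p = 0.248) were among them. None of 26 cholesterol synthesis genes passed either (median 0.06, camera adjusted p = 0.0813), including MSMO1 (0.42, adjusted p = 0.135) and TM7SF2 (-0.40, adjusted p = 0.196). In the list of sugar metabolism and insulin-responsive genes (10 tested, camera adjusted p = 0.157), TXNIP, an inhibitor of glucose uptake (-1.03, adjusted p = 0.0324), and IGFBP1, a binder of insulin-like growth factors (-0.98, adjusted p = 0.0421), fell.

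The proteasome and respiratory chain lists passed upward with camera's preset correlation but not with an estimated one, and none of their members passed over all genes tested. Of 25 proteasome genes 24 had a log2 fold change above 0 (median 0.17, camera adjusted p = 2.48e-09; adjusted p = 0.0596 with an estimated correlation), 3 of them past the threshold adjusted over the list alone. Of these lists only the proteasome passed with fry (adjusted p = 0.00632). PSMD4 had a log2 fold change of 0.37 (limma adjusted p = 0.0923) and PSMB4 0.36 (adjusted p = 0.111). Nuclear and assembly genes of complex IV, the copper-containing cytochrome c oxidase, had a median of 0.23 over 17 genes (camera adjusted p = 4.18e-07; adjusted p = 0.355 with an estimated correlation), with 6 adjusted over the list alone. COX6A1 stood at 0.31 (adjusted p = 0.205) and COX6C at 0.30 (adjusted p = 0.190). The other respiratory complexes had a median of 0.13 over 36 genes (camera adjusted p = 0.000330; adjusted p = 0.355 with an estimated correlation), with NDUFC2 at 0.30 (adjusted p = 0.202) and NDUFB3 at 0.25 (adjusted p = 0.246). The 30 ribosomal protein genes had a median of 0.09 (camera adjusted p = 0.000595; adjusted p = 0.763 with an estimated correlation), with RPSA at 0.24 (adjusted p = 0.238) and RPS14 at 0.29 (adjusted p = 0.377). Fold changes also followed gene length, with a median of 0.05 in the shortest of 10 length classes and -0.11 in the longest. The size of this trend depended on single libraries. Spearman's rho between fold change and length was -0.184 with all libraries, -0.041 without PA replicate 1 and -0.324 without PA replicate 3. With that length trend removed in each library, the ribosomal list lost its call (adjusted p = 0.130), as it did with quantile normalization (0.324) and without PA replicate 1 (0.562), while the proteasome (adjusted p = 1.75e-07), complex IV (7.38e-06), fatty acid oxidation (1.64e-06) and other respiratory lists (0.0131) did not. The 13 genes of mitochondrial DNA did not pass (median -0.07, camera adjusted p = 0.750), with MT-CO2 at 0.16 (adjusted p = 0.385) and MT-CO3 at -0.29 (adjusted p = 0.186). Neither did 19 genes of mitochondrial dynamics and biogenesis (median -0.06, camera adjusted p = 0.931), with UCP2 at -0.44 (adjusted p = 0.349) and TWNK at -0.35 (adjusted p = 0.413). The 19 TCA cycle genes did not pass either (median -0.03, camera adjusted p = 0.904). Among them SUCLG2 stood at -0.35 (adjusted p = 0.232) and IDH2 at 0.29 (adjusted p = 0.270).

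Among stress lists, those of the integrated stress response, autophagy and chaperones passed with camera's preset correlation, and none with an estimated one. Of 27 integrated stress response genes 3 rose (9 higher and 3 lower adjusted over the list alone; median 0.12, camera adjusted p = 8.99e-05; adjusted p = 0.366 with an estimated correlation). These were the asparagine synthetase gene ASNS (log2 fold change 0.67, limma adjusted p = 0.0140), CHAC1, a glutathione-degrading enzyme gene (0.63, adjusted p = 0.0227), and PHGDH, which starts serine synthesis (0.62, adjusted p = 0.0140). The autophagy and lysosome list had a median of only 0.01 (camera adjusted p = 0.0365; adjusted p = 0.849 with an estimated correlation) and lost its call without PA replicate 3 (adjusted p = 0.308) or HQF and copper replicate 2 (0.0599). It was also lost with the replicate number as a block, alone (0.0658) or with median-of-ratios scaling (0.0524). Of its 37 tested genes 3 rose (5 adjusted over the list alone). The autophagy receptor gene SQSTM1 rose from 2104 ± 120 to 3092 ± 62.2 TPM (0.56, adjusted p = 0.0198). The others were the lysosomal galactosidase gene GLA (0.62, adjusted p = 0.0236) and the protease gene CTSL (0.42, adjusted p = 0.0375). TFEB, a regulator of lysosomal genes, stood at 0.22 (adjusted p = 0.616). None of the chaperones of the endoplasmic reticulum passed, and their list was lower with the preset correlation (20 tested, median -0.13, camera adjusted p = 0.0111; adjusted p = 0.763 with an estimated correlation), with CALR at -0.23 (adjusted p = 0.193) and HYOU1 at -0.28 (adjusted p = 0.208). That call was lost with the block and median-of-ratios scaling together (adjusted p = 0.0757). The list of heat shock genes was lower too, with none past the threshold and 1 lower adjusted over the list alone (20 tested, median -0.14, camera adjusted p = 0.0409; adjusted p = 0.763 with an estimated correlation), with HSPB1 at -0.56 (adjusted p = 0.0774), CRYAB at -0.64 (adjusted p = 0.248) and HSPA1A at -0.20 (adjusted p = 0.309). The heat shock call was lost with median-of-ratios scaling (adjusted p = 0.111, and 0.121 with the block), with TMM scaling (0.112) and without PA replicate 1 (0.103) or 2 (0.0557) or HQF and copper replicate 2 (0.0702) or 3 (0.125).

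Among lists of growth and cell death genes, 2 passed with camera's preset correlation and none with an estimated one. The immediate-early list was lower (18 tested, median -0.26, camera adjusted p = 0.000468; adjusted p = 0.642 with an estimated correlation), with MYC at -0.57 (limma adjusted p = 0.0774) and JUND at -0.59 (adjusted p = 0.0617), and 2 lower adjusted over the list alone. So was the list of hypoxia and glycolysis genes (29 tested, median -0.14, camera adjusted p = 0.00257; adjusted p = 0.763 with an estimated correlation), with CA9 at -0.64 (adjusted p = 0.0895), ANKRD37 at -0.80 (adjusted p = 0.0646) and 6 lower adjusted over the list alone. Of 24 DNA replication genes only MCM7, a helicase subunit gene, fell, from 204 ± 8.42 to 107 ± 8.56 TPM (-0.93, adjusted p = 0.00684). The list had a median of -0.0034, against -0.047 for all genes tested, and camera's direction relative to the other genes was upward (adjusted p = 0.410). None of 24 mitosis genes (median -0.06, camera adjusted p = 0.904), 20 p53 targets (median -0.13, 0.0647), 20 apoptosis genes (median -0.03, 0.904), 11 replication histone genes (median 0.10, 0.0612) or 15 housekeeping genes (median -0.07, 0.260) passed over all genes tested. Past the threshold were 4 p53 targets, 2 apoptosis genes and 1 housekeeping gene lower and 2 histone genes higher adjusted over the list alone. The 2 mitosis genes with the smallest p moved in opposite directions, PLK1 (-0.31, adjusted p = 0.168) and CDC25C (0.35, adjusted p = 0.218). For p53 targets they were AEN (-0.45, adjusted p = 0.0788) and DDB2 (-0.37, 0.106). For apoptosis they were BCL2L1 (-0.44, adjusted p = 0.0902) and BBC3 (-0.54, 0.107). The histone genes were H4C8 (0.46, adjusted p = 0.112) and H1-2 (0.37, 0.144), and the housekeeping genes ACTB (-0.28, 0.118) and B2M (-0.27, 0.223).

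Of the 10 largest falls, 4 belonged to none of the fixed lists, IFIH1 among them. MYO7B, an unconventional myosin gene of the brush border, fell from 6.48 ± 1.07 to 1.13 ± 0.403 TPM (log2 fold change -1.82, limma adjusted p = 0.0124). PLAAT2, a phospholipase and acyltransferase gene, fell by 1.36 on the log2 scale (adjusted p = 0.0140) and UNC13D, a gene of granule release, by 1.25 (adjusted p = 0.0227). Both tested bile duct markers fell, KRT7 from 1394 ± 137 to 968 ± 46.9 TPM (-0.52, adjusted p = 0.04996) and MUC1 from 45.3 ± 11.5 to 18.6 ± 0.681 TPM (-1.21, adjusted p = 0.0227). The other 6 members of that list had means under 1 TPM. Marker lists of other cells were too low for camera. Of 10 fibroblast markers 2 were tested, TAGLN (-0.80, adjusted p = 0.214) and ACTA2 (-0.11, adjusted p = 0.804), with 1 lower adjusted over the list alone. Of 10 leukocyte markers 2 were tested, CD68 (-0.27, adjusted p = 0.457) and CD14 (0.11, adjusted p = 0.871). None of 8 endothelial markers was tested, and of 11 markers of other lines 3 were, among them PAX8 (-0.67, adjusted p = 0.145) and CDKN2A (-0.18, adjusted p = 0.415), again with 1 lower adjusted over the list alone.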

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

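The length and GC corrections and the omission of genes under 200 bases were chosen after seeing the data. The other alternatives were set before. The count of 114 genes moved to 18 without a filter on low values (30367 genes tested), 48 without a trend in the spread, 285 with the length correction (109 of the 114 shared) and 464 with the length and GC correction (103 shared). The remaining settings that keep all libraries gave 97 to 143 genes outside the fits with a block. Leaving out 1 library gave 6 to 1356 genes, and all 114 were among the 1356 called without PA replicate 3. The count of 49 genes at 2-fold moved to 19 with pseudocount 5, 12 without a filter, and 6 to 140 with 1 library left out. The causes of these changes were not tested. Of 46 named genes past the threshold, none changed direction. Still past the threshold were 14, 8 and 46 without PA replicate 1, 2 and 3, and 12, 2 and 3 without HQF and copper replicate 1, 2 and 3. Median-of-ratios or TMM scaling ended 11 of these calls each, no trend 26 and no filter 36. Of the 15 lists past the threshold, 0 passed with an estimated correlation (5 of all lists had an unadjusted p under 0.05) and 4 with fry, namely NRF2 targets, interferon, NF-kB and the proteasome. NRF2 targets gave 0.0596, interferon 0.155 and NF-kB 0.0852 with the estimated correlation. Under the other alternatives these 3 lists kept their direction and call. Lists that passed only under an alternative were p53 targets (4 settings), replication histones (3), cholesterol synthesis (1) and mitochondrial DNA (1). No pairing of the libraries by replicate number was evident, but 3 libraries per group cannot exclude one. Deviations from the group means correlated at 0.104, -0.058 and 0.113 for replicates 1, 2 and 3. Not every library correlated best with its own number (PA replicate 2 with HQF and copper replicate 1, 0.157). The replicate block gave 156 genes (99 shared), 95 with median-of-ratios scaling and 140 with the length correction.

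The share of the first principal component moved to 32.9% with pseudocount 0.1, 46.1% with pseudocount 5, 35.0% without a filter, 44.6% at 5 TPM or more, 50.9% for protein-coding genes and 44.9% for genes of at least 200 bases, and lay between 36.9% and 48.4% with 1 library left out. Reversed directions occurred only among lists and genes that had not passed, and none passed after the reversal. With median-of-ratios and TMM scaling the camera adjusted p was 0.966 and 0.975 for TCA cycle, mitosis and mitochondrial dynamics and 0.992 and 0.994 for cuproptosis. Mitochondrial dynamics also reversed at 5 TPM or more (0.924), with quantile normalization (0.978), length (0.918) and length and GC (0.947) corrections, and the block with the scaling (0.952, as mitosis) or the length correction (0.840). Apoptosis reversed at 5 TPM or more (0.975), zinc transport without a filter (0.771), and DNA replication (0.970) and hepatocyte genes (0.829) with fry. With 1 library left out, the adjusted p ranged from 0.628 to 0.990 for TCA cycle, 0.624 to 0.988 for apoptosis, 0.665 to 0.986 for cuproptosis, 0.787 to 0.985 for hepatocyte genes, 0.594 to 0.994 for mitochondrial dynamics, 0.252 to 0.990 for mitosis and 0.739 to 0.990 for zinc transport. Log2 fold changes then ranged from -0.087 to 0.21 for ATP7A, -0.011 to 0.17 for ATP7B, -0.091 to 0.31 for CD14, -0.25 to 0.0015 for MTF1, -0.13 to 0.064 for PPARA and -0.049 to 0.21 for SLC31A1. MTF1 stood at 0.025 with the length correction, with or without the block, and at 0.0096 with length and GC. Under quantile normalization MT-CO2 stood at -0.051 and PPARA at 0.0068. The cause was not tested. TPM gives no depth, so how depth limits these calls is unknown.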

Other observations

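The tests of annotation sets, the length correction, the tests of hepatocyte transcripts and short genes, the counts of splits and the choice of KRT17, KRT80, KRT8, ALPP, H19, MGST3, PGD, EPHX1 and POR came after the values were seen. Among 1815 gene sets from the authors' annotation, 61 were higher and 42 lower with camera's preset correlation, 0 with an estimated correlation, and 71 passed after the length correction. Keratinization genes were lower (23 tested, median log2 fold change -0.25, camera adjusted p = 0.00143; adjusted p = 0.9995 with an estimated correlation). Its 4 members past the threshold were keratins. KRT17 fell from 749 ± 53.7 to 374 ± 1.86 TPM (SD, n = 3 per group; log2 fold change -0.996, limma adjusted p = 0.00266). KRT80 changed by -0.94 (adjusted p = 0.0266), KRT8 by -0.59 (adjusted p = 0.0140) and KRT7 by -0.52 (adjusted p = 0.04996). The call of KRT17 held without 5 of the 6 libraries in turn, while those of KRT7, KRT8 and KRT80 held without only 1 of the 6. The calls of KRT7 and KRT8 were also lost with median-of-ratios scaling. Cell adhesion genes were lower as a set (174 tested, median -0.17, camera adjusted p = 0.00141; adjusted p = 0.9995 with an estimated correlation). Outside these sets, the placental alkaline phosphatase gene ALPP fell from 314 ± 33.8 to 148 ± 15.2 TPM (-1.08, adjusted p = 0.00921) and the imprinted RNA gene H19 from 280.2 ± 16.6 to 153 ± 6.96 TPM (-0.87, adjusted p = 0.00649).

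Sets of detoxification were higher. The KEGG glutathione metabolism set (37 tested, median 0.15, camera adjusted p = 3.02e-05; adjusted p = 0.9995 with an estimated correlation) held GCLM, CHAC1, PGD and the glutathione transferase gene MGST3 (log2 fold change 0.59, limma adjusted p = 0.0249) past the threshold. The set for xenobiotic metabolism by cytochrome P450 (23 tested, median 0.24, camera adjusted p = 1.92e-05; adjusted p = 0.9995 with an estimated correlation) held MGST3, CBR3 and EPHX1. The GO set for the glutathione metabolic process (21 tested, median 0.17, camera adjusted p = 0.0125) held no gene past the threshold. It lost its call after the length correction (camera adjusted p = 0.0951), while the KEGG glutathione set (0.00184) and the xenobiotic set (0.00276) kept theirs. POR, the electron donor of microsomal P450 enzymes, rose from 217 ± 5.57 to 293 ± 8.80 TPM (0.43, adjusted p = 0.0389).

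The near absence of hepatocyte transcripts in libraries labelled HepG2 was weighed first. Loss of these genes from the annotation is argued against, since 20 of the 25 hepatocyte genes had a value above 0 in at least 1 library, although 5 were listed at 0 throughout. A candidate explanation is that the sequenced cells were others than the label names or had lost hepatocyte expression. The highest TPM of 10 proteins secreted by liver cells, such as albumin, transthyretin and fibrinogen, was 0.69 in any library. Loss of hepatocyte transcripts under palmitic acid stays open and cannot be told apart from it, because there were 0 libraries without palmitic acid. Whether the table belongs to another experiment, which would put the treatment labels in doubt too, was not tested and stays open. The fold changes compare the 6 libraries under their labels as given.

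The second pattern was that lists moved, 5 of the 7 weighed by medians of at most 0.23, while fold changes followed gene length. Deviations of single libraries from the gene means correlated with length across genes at 0.39, 0.30 and -0.35 (Spearman's rho) in PA replicates 1, 2 and 3. They correlated at 0.09, -0.22 and -0.23 in HQF and copper replicates 1, 2 and 3, where genes are not independent replicates. With GC content they correlated at -0.12, -0.23 and 0.46 in PA replicates 1, 2 and 3. In HQF and copper replicates 1, 2 and 3 the values for GC content were -0.40, 0.02 and 0.21. With the trends on length and GC both removed, the other respiratory complexes had a camera adjusted p of 0.0208. The length trend as the whole cause is argued against for 6 lists. Their camera adjusted p after its removal was 1.98e-19 for NRF2 targets, 1.97e-17 for interferon, 1.75e-07 for the proteasome, 1.64e-06 for fatty acid oxidation, 7.38e-06 for complex IV and 0.0131 for the other respiratory complexes. For ribosomal proteins, with 0.130, the trend may account for the rise. Correlated variation between genes stays open for all 7, since none passed camera with an estimated correlation. The tests disagree for 3 of them: fry, which allows for such correlation but compares a list with no other genes, gave 0.00632 for NRF2 targets and the proteasome and 0.0143 for interferon.

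Of 13466 genes tested, 9 were listed at 0 in all 3 HQF and copper libraries and above 0 in all 3 PA libraries, 4 of them shorter than 200 bases, and 0 genes showed the opposite. The 4 short genes, of 116 to 149 bases and without symbols, were the most lowered of all genes called. Unstable TPM values of very short genes may account for them: 85.9% of the tested genes under 200 bases had a 0 in at least 1 library, against 1.04% of longer genes. A lower RNA level after HQF and copper cannot be told apart from this. Of 10 short genes with exactly 3 zeros, the 4 with zeros in the 3 treated libraries were these same genes, so their number decides nothing. Both stay open, and leaving these genes out did not lower the count of calls (132).

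The 6 libraries can be split into groups of 3 in 10 ways. In only 1 of the 10, the real one, did 114 genes pass, and the highest other count was 4. For changes of at least 2-fold the real count was 49 and the highest other 4 (1 split of 10 as large), and for lists 15 and 9 (1 of 10). Every other split also gave at least 3 lists past the threshold with camera's preset correlation. With 10 splits no share can fall under 0.05, so these counts are too few to say whether chance grouped the libraries.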
